A study of Mus musculus with 7 samples.

How the data were processed

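Gene expression was measured in hearts of mouse embryos that carried or lacked Myc, with 3 wild-type and 4 Myc-null samples, each on its own array. The sample titles place the hearts at embryonic day 13.5, while another label gives a window from day 12.5 to day 15.5. A free-text label describes embryos before their own genome is active, which does not match the other labels, and was not used. The group of each sample was taken from its title. The protocols speak of RNA of cardiac myocytes, but describe whole dissected hearts placed in Trizol and no separation of cells. The labels do not say how, when or in which cells Myc was removed, nor whether the samples of a group came from separate litters. The p-values therefore measure the spread between these 7 samples.

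Per the labels, 100 ng of total RNA was amplified and hybridised to Illumina mouse reference BeadChips, which carry bead-bound oligonucleotide targets, and the arrays were normalized by the rank-invariant method in BeadStudio. BeadStudio 1.5.0.34 is named in the submitters' processing notes and BeadStudio 1.5.1.3 in the headers of the per-array files. Per the file headers, the per-array files hold raw signal intensity with no normalization and a detection score per target, given as a fraction between 0 and 1 that equals 1 minus the detection p-value. The authors' deposited matrix holds normalized signal intensity, which can be negative. Set against the raw signals, each array's deposited intensity was a straight-line function of its raw signal, with factors from 0.809 to 1.43 and a largest deviation of 0.113 signal units. The authors' deposited table of difference scores gives 1 score for each of 24048 targets without naming its direction. A score of 13 in size is the usual BeadStudio equivalent of a p-value of 0.05.

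The deposited normalized signal was the main measurement, as fixed before the data were examined, and raw signals normalized with neqc were added as an alternative after the data were seen. The highest median of detected targets was 1.42 times the lowest across arrays, under the limit at which another normalization would have replaced the deposited scaling. Signals below a floor of 58.2 were set to that floor before log2 was taken. The floor is the median over arrays of the 5th percentile of signal among detected targets. Fold changes are on this scale and understate changes of dim genes. Targets detected (score of at least 0.99) on at least 3 of the 7 arrays were tested, and 4 bacterial control targets were left out. Of 24048 targets, 9441 passed. A gene with several passing targets was represented by the one with the highest mean. This left 9066 units, 65 of them at the floor on all 7 arrays, which stayed in the main test. The number of arrays limits the precision.

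The files give target identifiers without gene names. In identifiers with 1 or 2 leading zeros, the number after the prefix was looked up among the NCBI gene identifiers of the reference gene table (assembly GRCm38.p6), and 8884 of 9523 such numbers (93.3%) were gene identifiers. Without leading zeros 1136 of 10988 (10.3%) were, and with 3 or more leading zeros 0 of 3273 were, so neither class was named. As a check, 75 of 89 targets so named as ribosomal proteins were detected on 3 or more arrays, against 1 of 337 named as olfactory receptors. A further 9 targets were named through a RefSeq accession. In all 8893 targets were named for 7413 genes, and 15155 stayed unnamed. Every gene name below rests on this lookup, not on an annotation deposited with the arrays. Of the units tested, 3396 were named genes and 5670 were unnamed targets. The array files and labels name no genome build, and no coordinates are given.

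Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, 2-sided), with Benjamini-Hochberg adjustment over the 9066 units and a threshold of 0.05. Confidence intervals are at 95%. Single values were compared with an exact 2-sided permutation test over the 35 splits of the 7 arrays, whose smallest possible p is 0.0286. Of 27 gene lists fixed before the data were examined, 19 had at least 5 tested members and were tested with camera at a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run beside it. The genes named are Myc and its network, the 8 named genes with the smallest unadjusted p in each direction (as none passed the adjusted threshold), the 2 members with the smallest p of each list, the 2 brightest members of lists of other cell types, and Ccnd1, Ccnd2, Cdk4, Cdkn1a and Mycn. A gene that this rule selects is not reported here.

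All 7 arrays were on 1 BeadChip, with the wild-type samples at positions A to C and the Myc-null samples at positions E to H. Position on the chip and genotype cannot be told apart. A slide block was not possible. The steps were tested on simulated data for this comparison over 9066 units. A change was added to 200 genes on the measured arrays, after the floor and log2. The test recovered 0% of changes of 0.5 (log2), 39.9% of changes of 1 and 90.3% of changes of 2. In simulated arrays with Gaussian noise it recovered 0.025%, 51.3% and 89.9%. A simulated shift of 0.3 in the 63 ribosomal protein genes was found by camera in 20 of 20 simulations with Gaussian noise, with 1 call of another list. That noise was independent from gene to gene, while the measured ribosomal protein genes moved together (estimated correlation 0.63). These simulations therefore do not show how often camera would call such a list wrongly. Alternatives covered the floor, background model, scaling, filter, choice of target, moderation, array weights, a replicate block, each array left out, and thresholds.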

Results

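The arrays of 3 wild-type and 4 Myc-null hearts detected between 8573 and 9678 of 24048 targets each, and the comparison asks which transcripts in the embryonic heart differ when Myc, a transcription factor that drives growth and division, is missing. Myc itself could not be read. Its 1 target was detected on 0 of the 7 arrays, with a normalized signal of -18 ± 14.4 in wild-type (SD, n = 3) and -22.9 ± 2.91 in Myc-null hearts (SD, n = 4; exact permutation p = 0.6). The genotype labels therefore have no check in these arrays. The target's place relative to the deleted part of the gene is not given in the sources used here.

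No gene passed the test between Myc-null and wild-type hearts. By limma, 0 genes were higher and 0 were lower at an adjusted p under 0.05, and the smallest adjusted p was 0.76. At an unadjusted p under 0.05 there were 485 genes, 307 with higher and 178 with lower Myc-null means, where 453 are expected by chance. Without the 65 units that lay at the floor on all 7 arrays, an alternative chosen after seeing the data, there were 459 such genes, 317 of them higher, where 450 are expected, and the smallest adjusted p was 0.78. The direction of this excess depended on scaling, with 307 of 485 higher (63.3%) as deposited, 232 of 532 (43.6%) after quantile normalization and 217 of 516 (42.1%) after median scaling. The 4 Myc-null arrays lay on one side of the 3 wild-type arrays for 6.83% of genes, against 5.71% by chance. The median standard error was 0.18 and the median 95% interval reached 0.42 (log2) to either side. When changes were added to the measured arrays, 39.9% of changes of 1 (log2) and 0% of changes of 0.5 were recovered. Small changes were therefore not detectable with 7 arrays. The changes were added after the floor, so these rates leave out how the floor shrinks changes of dim genes.

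The genes with the smallest p are described by their values, since none passed. Senp1, which removes SUMO from proteins, had a signal of 155 ± 37.4 in wild-type (SD, n = 3) and 76.0 ± 13.2 in Myc-null hearts (SD, n = 4), a log2 difference of -1.01. Ctsj and Prl2c2, a cathepsin and a prolactin-family hormone best known from the placenta, had the largest differences of these genes, -1.63 and -1.37. Ctsj measured 392 ± 131 against 135 ± 73.4, and Prl2c2 212 ± 48.5 against 87.2 ± 48.3. Others with lower means were Ercc4, Alg1, Gtf3a and Tbc1d20, between -0.33 and -0.63. On the higher side stood Sfr1 and Sgo1, which act in DNA repair and in chromosome cohesion, with log2 differences of 0.83 and 0.76. Ints8, a subunit of the Integrator complex, had the largest of these, 1.05, from 65.3 ± 23.0 to 147 ± 35.2. Dennd10, Eif4g2, Mbtd1, Zfp931 and Srek1ip1 had differences from 0.54 to 0.86. In each gene of this paragraph all 4 Myc-null arrays lay on one side of the wild-type arrays. Apart from Zfp931, the genes on the higher side had wild-type means from 44.9 to 65.8, near the floor of 58.2. Their lowest array was wild-type 3, which stands apart from the rest, and Srek1ip1 was detected on only 1 wild-type array.

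**Figure D1:**
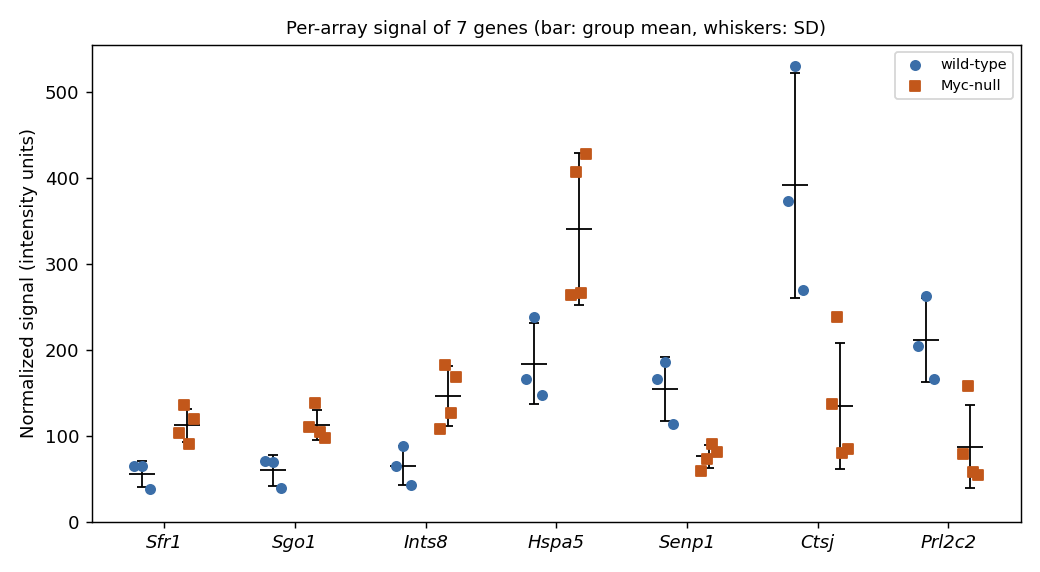
Normalized signal (intensity units, linear axis from 0) of 7 genes on each of the 3 wild-type (circles) and 4 Myc-null arrays (squares), with group means and SD. Sfr1, Sgo1, Ints8 and Hspa5 have higher and Senp1, Ctsj and Prl2c2 lower Myc-null means, and none passes the adjusted threshold.

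Among partners and antagonists of Myc, 6 of 17 listed genes could be tested and 0 passed, over all genes or adjusted over the list alone. Zbtb17, which encodes the Myc-binding repressor partner Miz-1, had a signal of 726 ± 57.4 in wild-type (SD, n = 3) and 595 ± 55.5 in Myc-null hearts (SD, n = 4), a log2 difference of -0.29. Mga, Mxi1 and Ruvbl2 had differences of 0.33, 0.31 and 0.09, and Mxd4 and Ruvbl1 of -0.12 and -0.13. These small differences depended on single arrays. Without wild-type 3 Mga was at -0.01 and Mxd4 at 0.22, and without wild-type 1 Mxi1 was at 0.06, Ruvbl2 at -0.05 and Ruvbl1 at -0.05. The Ruvbl1 values are of its brightest target, and its other target differed by 0.02. Mxd1 and Mlxip were detected on 0 arrays. Mycn, Ccnd2 and Cdk4 had no target that could be named.

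Cell cycle genes gave 0 calls in the main setting. Of 14 tested genes of the G1/S transition and DNA replication, 7 had higher and 7 lower Myc-null means. Pcna, the sliding clamp of DNA polymerases, had a log2 difference of 0.41 and E2f2 of -0.68. Ccnd1 differed by -0.03 and the CDK inhibitor Cdkn1a by -0.06 in the brightest target of each. The other Cdkn1a target differed by -0.38 (SE 0.27; limma adjusted p = 0.764 with every target tested). Among 11 mitotic genes 7 had higher means, with Nusap1 at 0.75 and Cdc20 at -0.27. The 3 tested CDK inhibitors and growth arrest genes included Gas5, at 0.61. Nusap1 and Gas5 were lowest on the wild-type 3 array, which stands apart from the rest, and were at 0.29 and 0.26 without it.

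Ribosomal protein genes were the exception among the lists, and the call depended on the test. Of 63 tested, 51 had higher and 12 lower Myc-null means, with a median log2 difference of 0.14, and 0 passed singly, over all genes or adjusted over the list alone. Camera called the list higher (adjusted p = 0.000284), but the adjusted p was 0.978 with an estimated correlation and 0.939 by fry. The members moved together from array to array (estimated correlation 0.63). Camera called this list, higher or lower, in 21 of the 35 splits of the arrays, and in 13 of them, the real one included, its adjusted p was as small as the real one. Over arrays, the list's mean deviation was -0.07 ± 0.10 in wild-type (SD, n = 3) and 0.10 ± 0.18 in Myc-null hearts (SD, n = 4; exact permutation p = 0.229). The highest array was Myc-null 4, at 0.34, and the lowest wild-type 1, at -0.14. Without Myc-null 4 camera's adjusted p was 0.325, and without wild-type 1 it was 0.151. After median scaling the list's median difference was 0.07, while the median of all units went from 0.03 to -0.03. Camera's adjusted p for the list was 0.00871 in that setting. Rps3a1 and Rpl26 had the smallest p, with differences of 0.51 and 0.36.

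The other growth and metabolic lists were not called in the main setting. Of 25 nucleolar and ribosome biogenesis genes 18 had higher means (adjusted p = 0.71 by camera), with Ebna1bp2 at 0.56 and Rrp1b at -0.59. Of 20 translation factors 13 had higher means (adjusted p = 0.485), among them Eif4g2 at 0.85. Nucleotide, polyamine and one-carbon metabolism had 6 of 10 higher (adjusted p = 0.958). Oxidative phosphorylation had 25 of 38 higher (adjusted p = 0.485), with Cox7b at 0.70, and fatty acid use had 5 of 6 higher (adjusted p = 0.71). Glycolysis had 11 of 14 lower (adjusted p = 0.414), with Hk1 at -0.66. Stress genes had 3 of 6 higher (adjusted p = 0.485), with the endoplasmic reticulum chaperone Hspa5 at 0.88, and p53 targets and apoptosis had 5 of 8 higher (adjusted p = 0.96). The 3 tested hypoxia-responsive genes all had lower means, Egln1 at -0.27, and were too few for a list test. Without wild-type 3 Ebna1bp2 was at 0.28 and Cox7b at 0.46, and without Myc-null 2 Hk1 was at -0.33 and Egln1 at -0.14. Camera called glycolysis lower without Myc-null 4 (adjusted p = 0.00561) and with a replicate block, where Myc-null 4 has no partner (adjusted p = 0.0198), and oxidative phosphorylation higher without Myc-null 2 (adjusted p = 0.00548). With an estimated correlation these adjusted p were 0.913, 0.95 and 0.783.

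No cardiac gene or list passed in the main setting. Of 9 contractile and calcium-handling genes 6 had higher means (camera adjusted p = 0.96), from Ckmt2 at -0.47 to the sodium-calcium exchanger Slc8a1 at 0.32. Cardiac transcription factors had 5 of 8 lower (adjusted p = 0.705), with Foxp1 at -0.21 and Tbx5 at -0.12. The 3 tested fetal and hypertrophic genes had higher means, Igf1 at 0.41. Without Myc-null 2 Ckmt2 was at -0.15, without wild-type 3 Slc8a1 was at 0.13 and Igf1 at 0.15, and without wild-type 1 Foxp1 was at -0.13 and Tbx5 at -0.08.

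Lists of other cell types gave 0 calls in the main setting and were uneven between arrays. The epicardial list had 5 of 8 lower (adjusted p = 0.414), with Krt19 at -0.69, and was called lower without Myc-null 2 (adjusted p = 0.0377 by camera, 0.783 with an estimated correlation). Endothelial genes had 5 of 8 lower (adjusted p = 0.71), with Emcn at 0.72, and mesenchymal genes 9 of 14 lower (adjusted p = 0.958), with Vcan at 1.03 and Eln at -0.64. Wild-type 3 was lowest for Emcn and Vcan, and without it Emcn was at 0.09, Vcan at 0.58 and Eln at -0.40. By list medians wild-type 3 was instead the highest array for mesenchymal (0.55), epicardial (0.37) and endothelial genes (0.21). Eln was at -0.39 without Myc-null 1. All 5 erythroid genes had higher means (adjusted p = 0.414), which included 1 array, Myc-null 2, with a list median of 1.06 against 0.00 to 0.03 on the other Myc-null arrays. Leukocyte genes had 2 of 5 higher (adjusted p = 0.981). Smooth muscle and neural genes had 2 tested members each and neighbouring tissues 3, such as Acta2 at -0.16, Gap43 at -0.06 and Apoa1 at 0.07. Without wild-type 1 Acta2 was at -0.01 and Apoa1 at -0.06, and without wild-type 3 Gap43 was at 0.02. Skeletal muscle and sex-linked lists had 0 tested members. With no filter on dim targets camera called the lists of glycolysis, G1/S, cardiac transcription factors, epicardium and endothelium lower (adjusted p from 0.000535 to 0.0436). In that setting 13050 of 22564 units lay at the floor on all arrays and rounding gave them a moderated t of 1.20, and without these units none of the 5 lists was called.

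**Figure D2:**
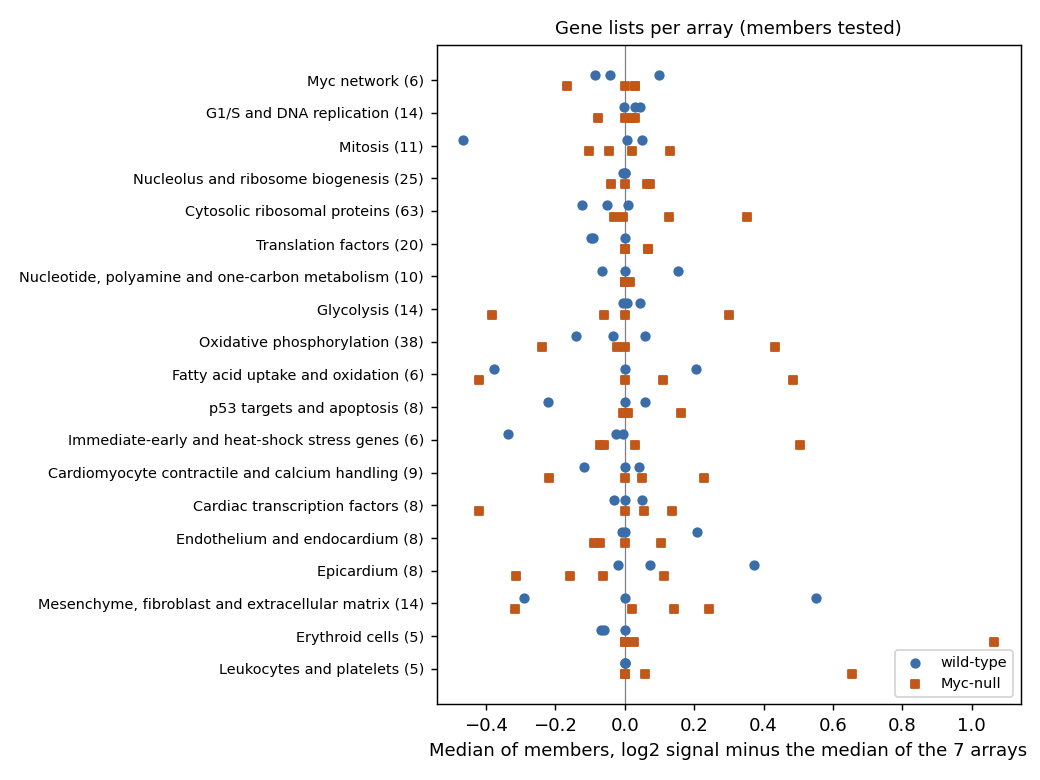
Median over the tested members of each of 19 gene lists, as log2 signal minus the gene's median over the 7 arrays, for wild-type (circles) and Myc-null arrays (squares). Myc-null 4 is highest for ribosomal proteins (0.35) and Myc-null 2 for erythroid genes (1.06).

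Wild-type 3 differed most from the other arrays. Its correlation with them across genes was 0.91 to 0.92, against 0.955 to 0.99 among the rest, and 791 of 9066 units lay at least 1 (log2) below their median there. Mki67, a proliferation marker, had a signal of 57.9 in wild-type 3 and at least 950 elsewhere. Mitotic genes did not move as a whole, with a list median of -0.47 in wild-type 3 but Cdc20 (1374) and Plk1 (2089) highest there. Myc-null 2 differed next most, with 92 units below and 150 above. Without both arrays, an alternative chosen after seeing the data, limma called 0 genes, with 366 at an unadjusted p under 0.05, and camera's adjusted p for ribosomal proteins was 0.0237, and 0.978 with an estimated correlation.

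**Figure D3:**
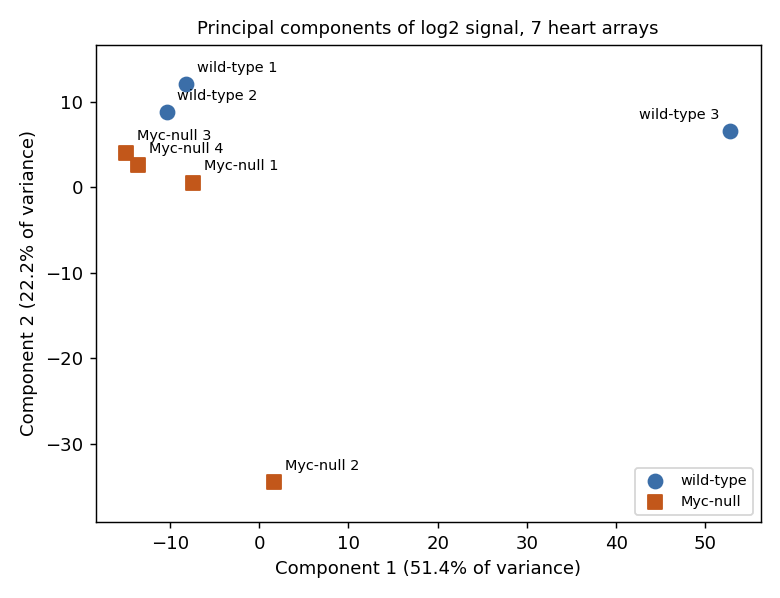
First and second principal components of log2 signal over 9066 units, in percent of variance, for wild-type (circles) and Myc-null arrays (squares). Wild-type 3 lies at 52.8 on the first (51.4%) and Myc-null 2 at -34.5 on the second (22.2%), apart from the other 5 arrays.

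The authors' deposited table marks 345 targets at a score of 13 or more and 102 at -13 or less. Its direction was read from the arrays. All 319 tested genes with positive scores this large had higher Myc-null means, and all 92 with negative scores had lower ones. Of these 411 genes in the authors' deposited table, 312 had an unadjusted p under 0.05 by limma and 0 an adjusted p under it. Scores in the authors' deposited table were also ranked among tested named genes, each by its brightest target, with clone and predicted gene symbols left out. Zfp931 (32.2) and Ints8 (29.7) had the highest of these scores in the authors' deposited table, and Tbc1d20 (-27.5) and Prl2c2 (-25.0) the lowest. Over all targets of the authors' deposited table the scores ran from -63.32 to 45.05. Wild-type 3 was the lowest of the 7 arrays for 214 of the 319 and the highest for 62 of the 92. Without that array the median log2 difference went from 0.51 to 0.39 in the 319 genes and from -0.45 to -0.37 in the 92.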

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

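The tests of wild-type 3, of red cells in Myc-null 2 and of Ctsj and Prl2c2 were chosen after the results were seen. The count of splits for ribosomal proteins was too. The cartilage test and the other counts of splits were set beforehand.

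Among 104 results tested in the 4 Myc-null arrays, 11 had 1 array apart from the other 3 by Dixon's ratio (critical value 0.829). In 4 of these the other 3 values were tied, so that any deviation counts as apart, which leaves 7. For independent Gaussian values chance gives about 1 in 20. List values are medians of deviations from a median over the 7 arrays, so many lie at or near 0. That rate need not hold for lists. Myc-null 2 was apart in the medians of the erythroid (1.06), smooth muscle (0.92) and leukocyte lists (0.65), and in the log2 signal of the mitochondrial creatine kinase gene Ckmt2 (6.34, against 7.50 to 7.69). Myc-null 4 was apart in log2 signal of Nme1 (12.82), Acadl (6.23), Tubb3 (5.96) and Aen (6.17), where for Acadl, Tubb3 and Aen the other arrays were tied at the floor, and in the nucleotide metabolism list (0.0137, the others tied at 0). Myc-null 1 was apart in the Myc network list (-0.17) and Myc-null 3 in the p53 list (0.16).

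Wild-type 3 had low signals of Mki67, Ncl and Hsp90aa1 and high signals of Gdf10 and Ccl21a. The authors' scaling is argued against as the cause, since after quantile normalization 633 units still lay at least 1 below their median, against at most 117 on another array. Dilution by another tissue is argued against for the genes that are low, as the 9 contractile genes had a median deviation of only -0.12 (SD 0.35). A loss of long transcripts stays open. The rank correlation of deviation with gene span, which is not transcript length, was -0.21 across genes in wild-type 3. The most negative other array was Myc-null 4, at -0.12. Myc-null 3 reached 0.30 in the opposite direction, so a correlation of this size also arose on another array. The quality of the RNA stays open too, as the 18S ribosomal RNA target had a signal of 2682 in wild-type 3 and 1523 in Myc-null 2, against 702 to 914 on the other 5 arrays. No biological explanation was tested.

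Myc-null 2 had the embryonic globin gene Hba-x at 24310, against 4388 to 8919 on the other arrays, and Col2a1, a collagen of cartilage, at 1698 against at most 381. An equal rise of Hba-x and Hbb-b2, as more red cells of the usual kind would give, is argued against by their log2 ratio. It was 0.79 there and -1.53 to -0.10 on the other 6 arrays (SD 0.49). However, Hbb-b2 (14100), Hbb-y (20140) and Hbb-b1 (379) were each highest in Myc-null 2, while Hba-a1 (63230) lay within the range of the other arrays. More red cells therefore stay open. Cartilage-like tissue may be present but could not be decided. The 4 cartilage genes looked at before were all high, and only 1 other, Sox5, was measurable, at 0.36. Genotype and stage were not tested.

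Ctsj and Prl2c2 were lower on all 4 Myc-null arrays without passing the adjusted threshold. Placental tissue in the wild-type samples could have brought them. Of 27 other placental genes listed, 11 were on the array by name. Of these, 0 were detected on 3 or more arrays, and 1 on a single array, which was a Myc-null one. This argues against placental tissue only as far as these 11 genes go, and their detection had been seen before the test was chosen. The authors' scaling is argued against, as the log2 differences stayed between -1.71 and -1.32 under 4 other scalings. Chance and the genotype stay open, and so does any property of these targets, whose sequences were not used here.

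The real count of 0 called genes by limma (highest other 2) cannot be tested with the 35 splits of the 7 arrays, since every split gives at least 0. Chance cannot be excluded for the other counts. Of the splits, 11 gave as many genes at an unadjusted p under 0.05 as the real 485 (highest other 1190, with wild-type 3, Myc-null 2 and Myc-null 4 as a group). All 35 splits shifted at least as many lists by camera as the real 1 (highest other 5). For ribosomal proteins alone, 13 splits gave a camera adjusted p as small as the real 0.000284 (smallest other 9.81e-19), so chance cannot be excluded for that call.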

How the results depend on the processing

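Leaving out wild-type 3 with Myc-null 2, neqc on raw signals, leaving out units with the same value on every array, and an estimated correlation with arrays left out, with no filter or with the replicate block were chosen after seeing the data. Genes higher and genes lower in Myc-null stayed at 0 by limma under all 28 alternatives run and at an adjusted p under 0.1 or with a 1.5-fold minimum, with 302 to 718 genes at an unadjusted p under 0.05. The smallest adjusted p under any of them was 0.0662, with a higher floor, and 0.756 there without units at that floor on all arrays. Of 2171 values of 79 named genes, 0 passed the threshold, and 59 changed sign without passing in either setting. The deposited matrix in place of the per-array files is the main setting itself, and a slide block could not be run with 1 BeadChip. The ribosomal list was called in 23 of 28 camera settings at the preset correlation, with medians from 0.06 to 0.19 and adjusted p from 2.91e-07 to 0.325. With no filter on dim targets 5 other lists (glycolysis, G1/S, cardiac transcription factors, epicardium and endothelium) were called lower and ribosomal proteins were not (adjusted p 0.245). These calls came from units at the floor on all arrays, since without them only ribosomal proteins were called (adjusted p 0.000237). Array weights (adjusted p 0.0785) and fry gave 0 lists, for which the cause was not tested. An estimated correlation gave 0 lists too. There the only setting changed from the main test was the correlation, which for ribosomal proteins was 0.63 in place of 0.01. With each array left out, 0 to 3 lists were called. None was called without wild-type 1. Without Myc-null 4 the only list was glycolysis (lower, adjusted p 0.00561), and without Myc-null 2 oxidative phosphorylation (higher) and epicardium (lower) joined ribosomal proteins. With an estimated correlation camera called 0 lists with any 1 array left out (smallest adjusted p 0.783) or without wild-type 3 and Myc-null 2 (0.978). It also called 0 with no filter (smallest adjusted p 0.306) or with the replicate block (0.95). After each group's mean was subtracted, same-numbered arrays correlated at 0.17, -0.26 and -0.31, which gave no sign of pairing by replicate number. Such deviations offset each other within a group, so these values cannot exclude pairing. The replicate block gave 0 genes and 1 list, glycolysis in place of ribosomal proteins. The Myc difference of -4.92 signal units lay between -11.8 and 2.51 with each array left out, turning positive without wild-type 3, and passed no permutation test (p 0.0667 to 0.75 over its alternatives). At the floor it has no value. In the authors' deposited table, 103 targets passed a score of 20 against 447 at 13. Signal over background limits dim genes, with 13261 of 24048 targets detected on no array.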

Other observations

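Cox7a2l, chosen after its values were seen, had a signal of 1353, 1329 and 1581 in wild-type 3, Myc-null 3 and Myc-null 4 and of 62.4 to 116 on the other 4 arrays. The atrial light chain gene Myl7 measured 7628 in wild-type 2 and 8114 in Myc-null 3, against 13790 to 17150 elsewhere, and the atrial myosin gene Myh6 was lowest on the same arrays, at 792 and 951. Gdf10, Ccl21a and Krt8 were high in both wild-type 3 and Myc-null 2, with Gdf10 at 1353 and 937 against 64.6 to 190 on the other arrays.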
